A study of Citrus sinensis x Citrus trifoliata with 12 samples.

How the data were processed

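Single-colour oligonucleotide arrays were read for 12 plant RNA samples of Carrizo citrange, 3 in each of 4 groups: wild type in normoxia, wild type after anoxia, and the same for a transgenic line carrying Mybleu. Groups and replicate numbers came from the sample labels. Per the labels' protocols, 6 µg of total RNA was labelled with Cy5 for each array. The tissue is given as root in one label field, while the extraction protocol names leaves, so the tissue stays unsettled here. The treatment protocol describes 24 h of nitrogen and also a recovery of 2 weeks, and does not say at which of these points RNA was taken.

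The deposited scanner files hold, for each of 94928 spots, the median foreground and the median local background intensity in linear scanner units, per the file headers, and the percent of saturated pixels of a spot, also as deposited. They were written by GenePix Pro 7.0.10, per the file headers, and are neither background-corrected nor normalized. The authors' value table, deposited with the series, holds a processed intensity for 7336 of the 7851 probe names on a linear scale. How it was made is not given in the sources used here. Its column medians were 563, 347 and 414 in wild-type normoxia, 141, 1842 and 187 in wild-type anoxia, 355, 215 and 345 in transgenic normoxia and 128, 496 and 576 in transgenic anoxia, so its columns are not on one scale. Its highest value was 236581. Each column correlated best with the values of its own array on the log2 scale, so the match of columns to arrays and the direction are known, while its scaling is not. 0 columns of that table lay outside the 12 samples.

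The array carries 7697 target probes of 35 to 40 bases, each in 11 to 15 spots (median 11), 47 negative-control probes, 87 probes named by sequence accession, 19 factory probes and 1617 empty spots. The files pair no probe with a gene name or product, so results are given per probe, by probe ID and sequence. The 21 gene lists fixed before the data were examined select genes by product description, so none could be measured, and no probe could be assigned to the transgene.

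Foreground was corrected with normexp and an offset of 50 in limma 3.58.1 under R 4.3.3. Target, accession-named and negative-control spots were quantile normalized between arrays and taken to log2, and the spots of a probe were averaged. A target probe was tested if its value exceeded the 95th percentile of the negative-control spots on at least 3 of the 12 arrays, which left 3641 probes and took out 4056. A group-means model of all 12 arrays, with 8 residual degrees of freedom and 6.56 prior degrees of freedom, was fitted with lmFit and eBayes. It gave the anoxia effect in each line, the line difference in each condition and the difference of the anoxia effects (interaction). P-values were adjusted by the Benjamini-Hochberg method over the tested probes, and a probe is called at an adjusted p below 0.05. The accession-named probes were fitted separately by the same model. The number of arrays limits the precision: the median 95% confidence interval of a 2-group log2 fold change was ±0.57, and ±0.80 for the interaction. P-values measure the spread between replicates, pooled over all groups. The labels do not say whether replicates came from separate cultures, so this spread may be technical.

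The named probes follow a rule set before the data were examined: in each 2-group comparison, the called probes with non-overlapping groups that had the largest rise (2 probes) and the largest fall (2 probes). Where a group lay below the limit on all 3 arrays, the fold is a lower bound, from the brighter group's mean over the mean, per array, of the higher of the lowest value among probes above the limit and the probe's own value. For id_1752_373_39_S, id_3921_1184_35_X2, id_4_83_35_X3 and id_2728_272_37_X3, 2 of 3 arrays of the dimmer group exceeded the limit in the comparison that named them. Their folds there are as fitted, with a value below the limit included. A probe was counted as saturated on an array if most of its spots had over 50 percent of their pixels saturated. Of the target probes, 37 were saturated on at least 1 array, none of them a named one.

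The image records in the file headers show 4 physical chips, each used for 2 to 4 of the arrays, and 8 scan days. Each chip held more than 1 group, so the chip was fitted as a fixed and as a random block. On 1 scan day 2 groups were scanned, and the day was fitted as a random block. All 3 wild-type anoxia arrays were scanned on 1 day, without another group, so the day and this group cannot be told apart and the block cannot part them. Replicate numbers were checked by correlating, across probes, the deviations of same-numbered arrays from their group means. In wild type the correlations of normoxia with anoxia were 0.13, 0.14 and 0.13, all over 0.1, the second between 2 arrays of 1 chip. The numbers were therefore treated as possible pairs there, from the data and not from a stated design. In the transgenic line the correlations were -0.03, -0.15 and 0.04, and in neither line comparison were all 3 over 0.1. The main fit left any pairing out. Pairs entered only a set of splits and the replicate block, which was fitted over all groups.

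The alternatives covered background correction, normalization, the authors' values, filters, replicate block, arrays in the fit, variance model, array weights, chip and scan day, a 2-fold threshold, the median of spots and leaving out each array. Chosen after the data were examined were the removal of a spatial trend (the medians, in 20 by 12 tiles and 3 rounds, of spot minus probe mean), the same with the chip as a block, quantile normalization of the authors' values, and a fit without 2 arrays of raised background. The model was tested on simulated data made from the 3641 probes' means and spreads with 200 probes changed. For the wild-type anoxia comparison it recovered 10.4 percent of the probes changed 1.5-fold, 49.3 percent of those changed 2-fold and 95.5 percent of those changed 4-fold, with 7 false calls among 110. For the interaction it recovered 8.96 percent at 2-fold and 74.2 percent at 4-fold. The simulated arrays varied independently, with the same spread in every group and no chip, scan-day or spatial effect. These rates may therefore not hold for the real arrays.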

Results

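Transcript levels were compared between wild-type Carrizo citrange, a hybrid of sweet orange and trifoliate orange used as a rootstock, and a transgenic line of it carrying Mybleu, a rice gene of the MYB transcription factor family. Plants 3 weeks old were kept in normoxia or flushed for 24 h with 100% nitrogen at 5 l per h, and each of the 4 groups was measured on 3 arrays. Median foreground ranged from 323 to 798 scanner units over the arrays. Local background lay between 26 and 128 on 10 arrays, but was 502 on wild-type anoxia replicate 1 and 454 on wild-type anoxia replicate 3. Between 1912 target probes (wild-type anoxia replicate 2) and 3751 (transgenic anoxia replicate 3) lay above the negative-control limit. Saturated pixels were found in 0.0294 to 0.357 percent of target spots. Replicates correlated across the tested probes at 0.89 to 0.94 in wild-type normoxia, 0.83 to 0.93 in wild-type anoxia, 0.97 to 0.98 in transgenic normoxia and 0.93 to 0.94 in transgenic anoxia.

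Brightness changed along the rows of many arrays. From the first to the last of 7 row bands, the spots of wild-type anoxia replicate 2 fell by 2.82 log2 units relative to their probes' means, the range being over 1 on 6 of the 12 arrays. The spots of one probe had a median SD of 1.14 on that array, against 0.13 on the array with the lowest SD. With the spatial trend removed, it was 0.35 on that array.

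**Figure D1:**
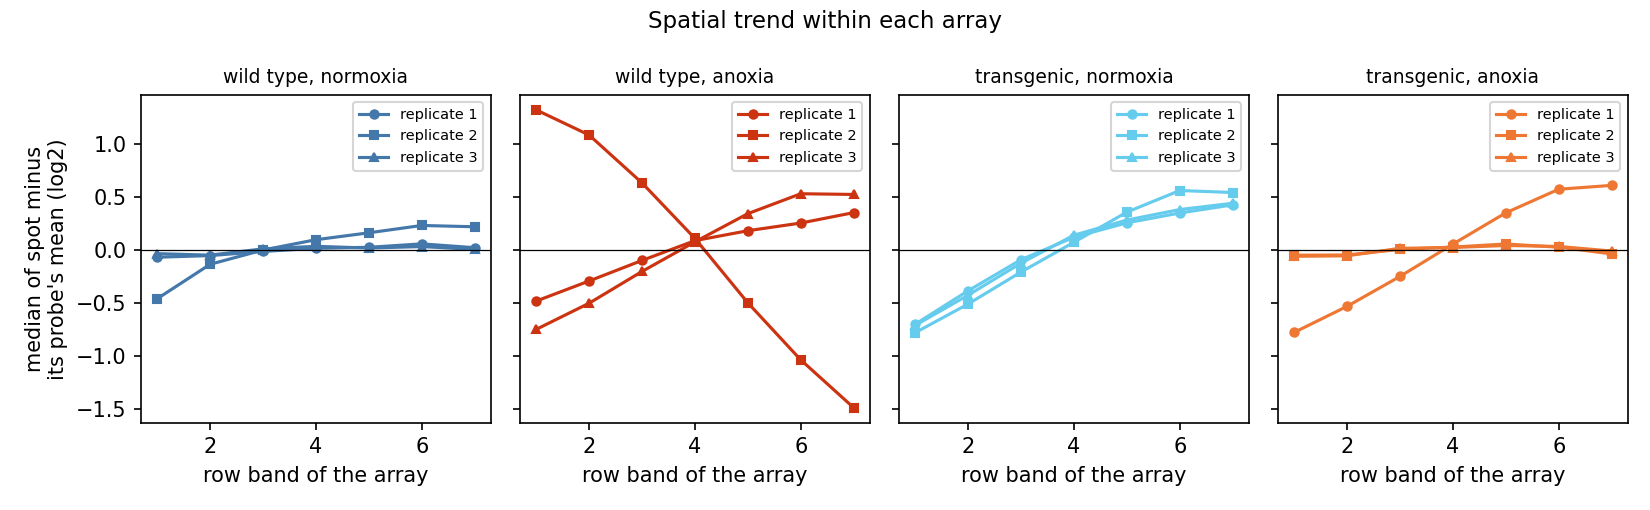
Median of spot minus its probe's mean, in log2 units, in 7 bands of rows from the first to the last row of the array, for the 3 replicates of each group. Wild-type anoxia replicate 2 runs from 1.33 down to -1.49, opposite to the other arrays with a trend.

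The transgene could not be checked, since the files pair no probe with it. Among the 87 accession-named probes, 9 lay above the limit on all 12 arrays and 56 on none. In the fit of these probes with limma, which kept those below the limit, 0 were called in any of the 5 contrasts. At an unadjusted p under 0.05 in that fit there were 16 for the lines in normoxia and 6 for the lines in anoxia. There were 16 for anoxia in wild type, 2 for anoxia in the transgenic line and 18 for the interaction.

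The first question was which transcripts anoxia changed in wild-type plants. Probe id_1874_728_35_X2 (sequence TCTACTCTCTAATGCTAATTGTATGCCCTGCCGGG) rose from below the limit on all 3 normoxia arrays to a log2 level of 11.76 ± 0.20 (SD, n = 3), at least 6.22-fold, with an adjusted p = 1.11e-06. Probe id_1752_373_39_S (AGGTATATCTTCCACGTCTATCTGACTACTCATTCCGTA) rose 10.4-fold, from 8.99 ± 0.35 to 12.36 ± 0.62 (SD, n = 3), with a log2 fold change of 3.37, SE 0.31 and adjusted p = 1.18e-05. Probe id_3921_1184_35_X2 (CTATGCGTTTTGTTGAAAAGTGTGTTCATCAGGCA) fell from 13.05 ± 2.06 to 9.60 ± 0.62 (SD, n = 3), a log2 fold change of -3.44 with SE 0.68 and adjusted p = 0.00418. Its size rests on wild-type normoxia replicate 3: the log2 fold change was -2.26 without that array and -4.09 without wild-type normoxia replicate 1, and with the chip as a fixed block it was -3.18, past the threshold no longer (adjusted p = 0.0863). Probe id_3598_1736_36_X3 (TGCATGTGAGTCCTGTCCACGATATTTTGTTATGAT) fell from 14.06 ± 1.11 to 10.71 ± 0.71 (SD, n = 3), a log2 fold change of -3.35 with SE 0.44 and adjusted p = 0.000182, which was -2.72 without wild-type normoxia replicate 3. In all, 475 of 3641 probes were called, 73 higher and 402 lower in anoxia. In 122 of them, 6 higher and 116 lower, the dimmer group lay below the limit on all its arrays. With these at their bound, or as no change where there was no bound (14 probes), the median folds were at least 2.14 and 2.10. At least 4-fold changes then numbered 9 higher and 36 lower. The groups did not overlap for 25.8 percent of the tested probes, where chance gives 10 percent.

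The median log2 fold change of all tested probes in wild type was -0.11. Cyclic loess normalization put this median at 0.02 and gave 133 probes higher and 290 lower. The main fit did not pair the replicates. With the replicate number as a block 397 probes were called, 61 higher and 336 lower. With the chip as a fixed block 241 probes were called, 27 higher and 214 lower, and the authors' values on log2, which are not on one scale, gave 1 call. Leaving out wild-type anoxia replicate 1 gave 259 (28 higher, 231 lower), replicate 2 gave 443 (122 higher, 321 lower) and replicate 3 gave 718 (190 higher, 528 lower), and leaving out wild-type normoxia replicate 1 gave 278 (38 higher, 240 lower). All 3 wild-type anoxia arrays were scanned on 1 day, on which no other group was scanned. Scan day therefore cannot be told apart from anoxia in wild type, from the line in anoxia or from the interaction, and a random block does not remove it; 142 of the 475 probes were also called in the transgenic line, whose arrays were scanned on other days. On the chip that held both wild-type groups, 371 of the 441 probes called without its 2 arrays had the same direction.

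The same question was asked of the transgenic line. Probe id_7846_107_35_X2 (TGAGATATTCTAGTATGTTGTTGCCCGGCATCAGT) rose from below the limit on all 3 normoxia arrays to 11.68 ± 0.53 (SD, n = 3), at least 4.96-fold, with adjusted p = 3.60e-06. Probe id_2982_369_35_X4 (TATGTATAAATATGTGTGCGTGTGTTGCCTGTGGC) rose 13.2-fold, from 11.05 ± 0.54 to 14.78 ± 0.55 (SD, n = 3), with a log2 fold change of 3.73, SE 0.37 and adjusted p = 1.80e-05. Probe id_4_83_35_X3 (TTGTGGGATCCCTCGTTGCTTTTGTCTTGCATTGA) fell from 12.22 ± 0.55 to 9.32 ± 0.17 (SD, n = 3), a log2 fold change of -2.90 with SE 0.38 and adjusted p = 0.000259. Probe id_5587_101_37_X2 (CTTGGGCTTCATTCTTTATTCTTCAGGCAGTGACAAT) fell from 12.86 ± 0.15 to 10.09 ± 0.07 (SD, n = 3), a log2 fold change of -2.77 with SE 0.25 and adjusted p = 1.16e-05. In all, 283 probes were called, 134 higher and 149 lower. With the 84 probes whose dimmer group lay below the limit at their bound (5 had none), the median folds were at least 2.17 and 2.20, and at least 4-fold changes numbered 25 higher and 14 lower. The groups did not overlap for 37.1 percent of the probes, against 10 percent by chance.

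With the chip as a fixed block 65 probes were called in the transgenic line, 23 higher and 42 lower, and the authors' values on log2 gave 3 calls. Within the chip that held both transgenic groups, 103 of the 106 probes called without its 2 arrays had the same direction. Leaving out transgenic anoxia replicate 3 gave 119 calls, and transgenic normoxia replicates 1, 2 and 3 gave 135, 116 and 145. Leaving out wild-type anoxia replicate 2, which enters only through the shared spread, gave 439. With only the 6 arrays compared in the fit, 704 probes were called in the transgenic line and 180 in wild type. Which line had more calls thus depended on the arrays that gave the spread.

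The differences between anoxia and normoxia were related in the 2 lines, probe by probe. Across the tested probes, which are not independent replicates, the log2 fold changes of the lines correlated at r = 0.56 (jackknife SE 0.14), although the 2 contrasts share no arrays. Of the probes called higher, 38 were shared, where independent lists would share 2.69, and of those called lower 104 were shared, against 16.5. Of the shared calls 0 went in opposite directions. Probe id_1874_728_35_X2 rose at least 8.33-fold in the transgenic line and at least 6.22-fold in wild type, and lay below the limit on all normoxia arrays of both lines, so the sizes of its rises cannot be compared. In the transgenic line, probe id_1752_373_39_S rose by 3.06 on the log2 scale (SE 0.31) and id_3598_1736_36_X3 fell by 2.20 (SE 0.44), while id_3921_1184_35_X2 was not called there (log2 fold change -1.23, SE 0.68, adjusted p = 0.303). The probes named for the transgenic line were all called in the same direction in wild type. There id_7846_107_35_X2 was at least 2.88-fold and id_2982_369_35_X4 2.52-fold higher. Probe id_4_83_35_X3 was at least 3.69-fold and id_5587_101_37_X2 5.28-fold lower.

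**Figure D2:**
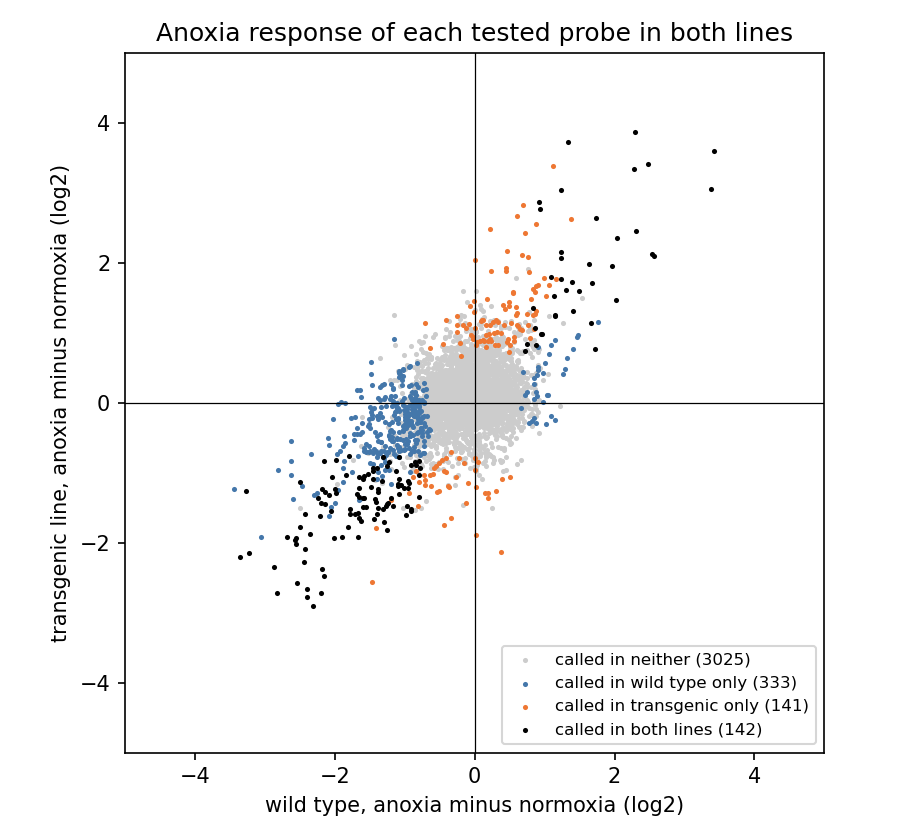
Log2 fold change of anoxia over normoxia in wild type (horizontal) and in the transgenic line (vertical) for each of the 3641 tested probes, coloured by the line in which it was called. The 142 probes called in both lines lie to the lower left and the upper right of the origin, and r is 0.56.

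Whether the response differed between the lines was tested by the interaction, and limma called 0 of 3641 probes, with 619 at an unadjusted p under 0.05 and a smallest adjusted p of 0.106. A call in one line alone therefore does not establish a difference between the lines, nor do these counts exclude one, since on simulated data the fit recovered 8.96 percent of 2-fold interactions. The scan day of the wild-type anoxia arrays enters this contrast, and so does the chip. All 4 arrays of 1 chip were wild-type normoxia or transgenic anoxia. All 3 arrays of another were wild-type anoxia or transgenic normoxia. A chip block can therefore separate the chip from this contrast only in part. With the chip as a fixed block limma again called 0, with 190 at an unadjusted p under 0.05. As a random block the chip also left 0, with 248. The probe id_4079_102_35_X4 rose by 3.04 in the transgenic line and 1.23 in wild type on the log2 scale, a difference of 1.81 (SE 0.35) with adjusted p = 0.106. Leaving out transgenic anoxia replicate 1, which left that group on 1 chip, gave 87 calls. Wild-type normoxia replicate 3 left out gave 5 and wild-type normoxia replicate 1 gave 1. Array weights gave 468 calls, 369 with a higher response in the transgenic line, scan day as a random block gave 56 and the stricter filter 17.

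The next comparison was of the lines in normoxia, where 2 probes were called, both lower in the transgenic line. Probe id_390_206_40_S (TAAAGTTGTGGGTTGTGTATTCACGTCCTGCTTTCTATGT) was at 14.19 ± 0.74 in wild type and 11.98 ± 0.53 in the transgenic line (SD, n = 3), a log2 fold change of -2.20 with SE 0.34 and adjusted p = 0.0215. Probe id_4079_102_35_X4 (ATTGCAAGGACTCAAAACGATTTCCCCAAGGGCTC) was at 12.46 ± 0.33 and 10.86 ± 0.13 (SD, n = 3), a log2 fold change of -1.60 with SE 0.25 and adjusted p = 0.0215. In anoxia their line differences were -1.36 (SE 0.34) and 0.21 (SE 0.25), neither past the threshold. At an unadjusted p under 0.05 there were 356 probes, and the groups did not overlap for 26.5 percent of the tested probes, against 10 percent by chance. With the chip as a fixed block 0 were called by limma, with 154 at an unadjusted p under 0.05, and no chip held both groups. The log2 fold changes in that fit were -2.16 (SE 0.54) for id_390_206_40_S and -1.20 (SE 0.32) for id_4079_102_35_X4. Array weights gave 73 calls, 19 higher and 54 lower. The calls were also lost with the chip as a random block, with the replicate block, with 75th percentile scaling, with cyclic loess, with no filter, with the median of spots, with the authors' values on log2, with only the 6 arrays compared, without both arrays of raised background, and without wild-type normoxia replicate 2 or 3, transgenic anoxia replicate 2 or any one transgenic normoxia array, and numbered 5 without transgenic anoxia replicate 1. With 75th percentile scaling the 2 log2 fold changes were -2.23 and -1.62, and with cyclic loess -2.28 and -1.67.

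After anoxia 22 probes differed between the lines, 19 higher and 3 lower in the transgenic line. In 8 of them the dimmer group lay below the limit on all its arrays, among them all 3 lower ones, and with these at their bound (1 had none) the median fold of the higher ones was at least 2.67. The groups did not overlap for 16.5 percent of the tested probes, against 10 percent by chance. Probe id_1707_728_35_X4 (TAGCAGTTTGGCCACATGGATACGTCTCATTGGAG) was at 11.02 ± 0.24 in the transgenic line (SD, n = 3) and below the limit on all 3 wild-type arrays, at least 2.93-fold higher, with adjusted p = 0.0163. This probe had similar means in both lines in normoxia (10.99 ± 0.79 and 11.01 ± 0.23; log2 difference 0.01, SE 0.32), and it was at least 2.88-fold lower in anoxia in wild type (adjusted p = 0.00125), with an interaction adjusted p = 0.106. Probe id_2728_272_37_X3 (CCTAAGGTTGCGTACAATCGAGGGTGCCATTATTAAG) was at 11.61 ± 0.24 against 9.71 ± 0.39 (SD, n = 3), a log2 fold change of 1.90 with SE 0.32 and adjusted p = 0.0163. Probe id_915_267_37_X8 (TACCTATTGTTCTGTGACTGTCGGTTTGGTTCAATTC) was below the limit on all 3 transgenic arrays and at 10.39 ± 0.43 in wild type (SD, n = 3), at least 2.36-fold lower in the transgenic line, with adjusted p = 0.0163. Probe id_6134_26_37_S (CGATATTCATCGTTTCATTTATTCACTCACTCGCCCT) was likewise below the limit in the transgenic line and at 9.87 ± 0.22 in wild type, where 2 of 3 arrays exceeded the limit, at least 1.65-fold lower with adjusted p = 0.0292. Its call was lost in 14 of 29 alternatives (adjusted p from 0.00309 to 1.00), among them the replicate block, with adjusted p = 0.0567, where 1 probe was called lower.

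With the chip as a fixed block limma called 0 of these line differences in anoxia, with 324 at an unadjusted p under 0.05. On the chip that held arrays of both lines in anoxia, the 11 probes called without its 2 arrays all had the direction of the call. The median log2 difference of these 11 probes between those 2 arrays, in the direction of the call, was 0.90, against 1.74 in the fit without the 2 arrays, and across the tested probes their difference correlated at 0.25 with the fold changes fitted without them. The wild-type arrays were scanned on a day of their own, so this comparison cannot be told apart from scan day. Leaving out any one of wild-type anoxia replicates 1 and 2 or of the 3 transgenic anoxia arrays gave 0 calls, as did the median of spots and the authors' values on log2. Wild-type anoxia replicate 3 left out gave 36, wild-type normoxia replicate 3 gave 51 and replicate 2 gave 14, and transgenic normoxia replicates 1 and 2 gave 12 and 13. The line differences in normoxia and in anoxia correlated across probes at r = -0.01 (jackknife SE 0.33), and 0 probes were called in both.

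**Figure D3:**
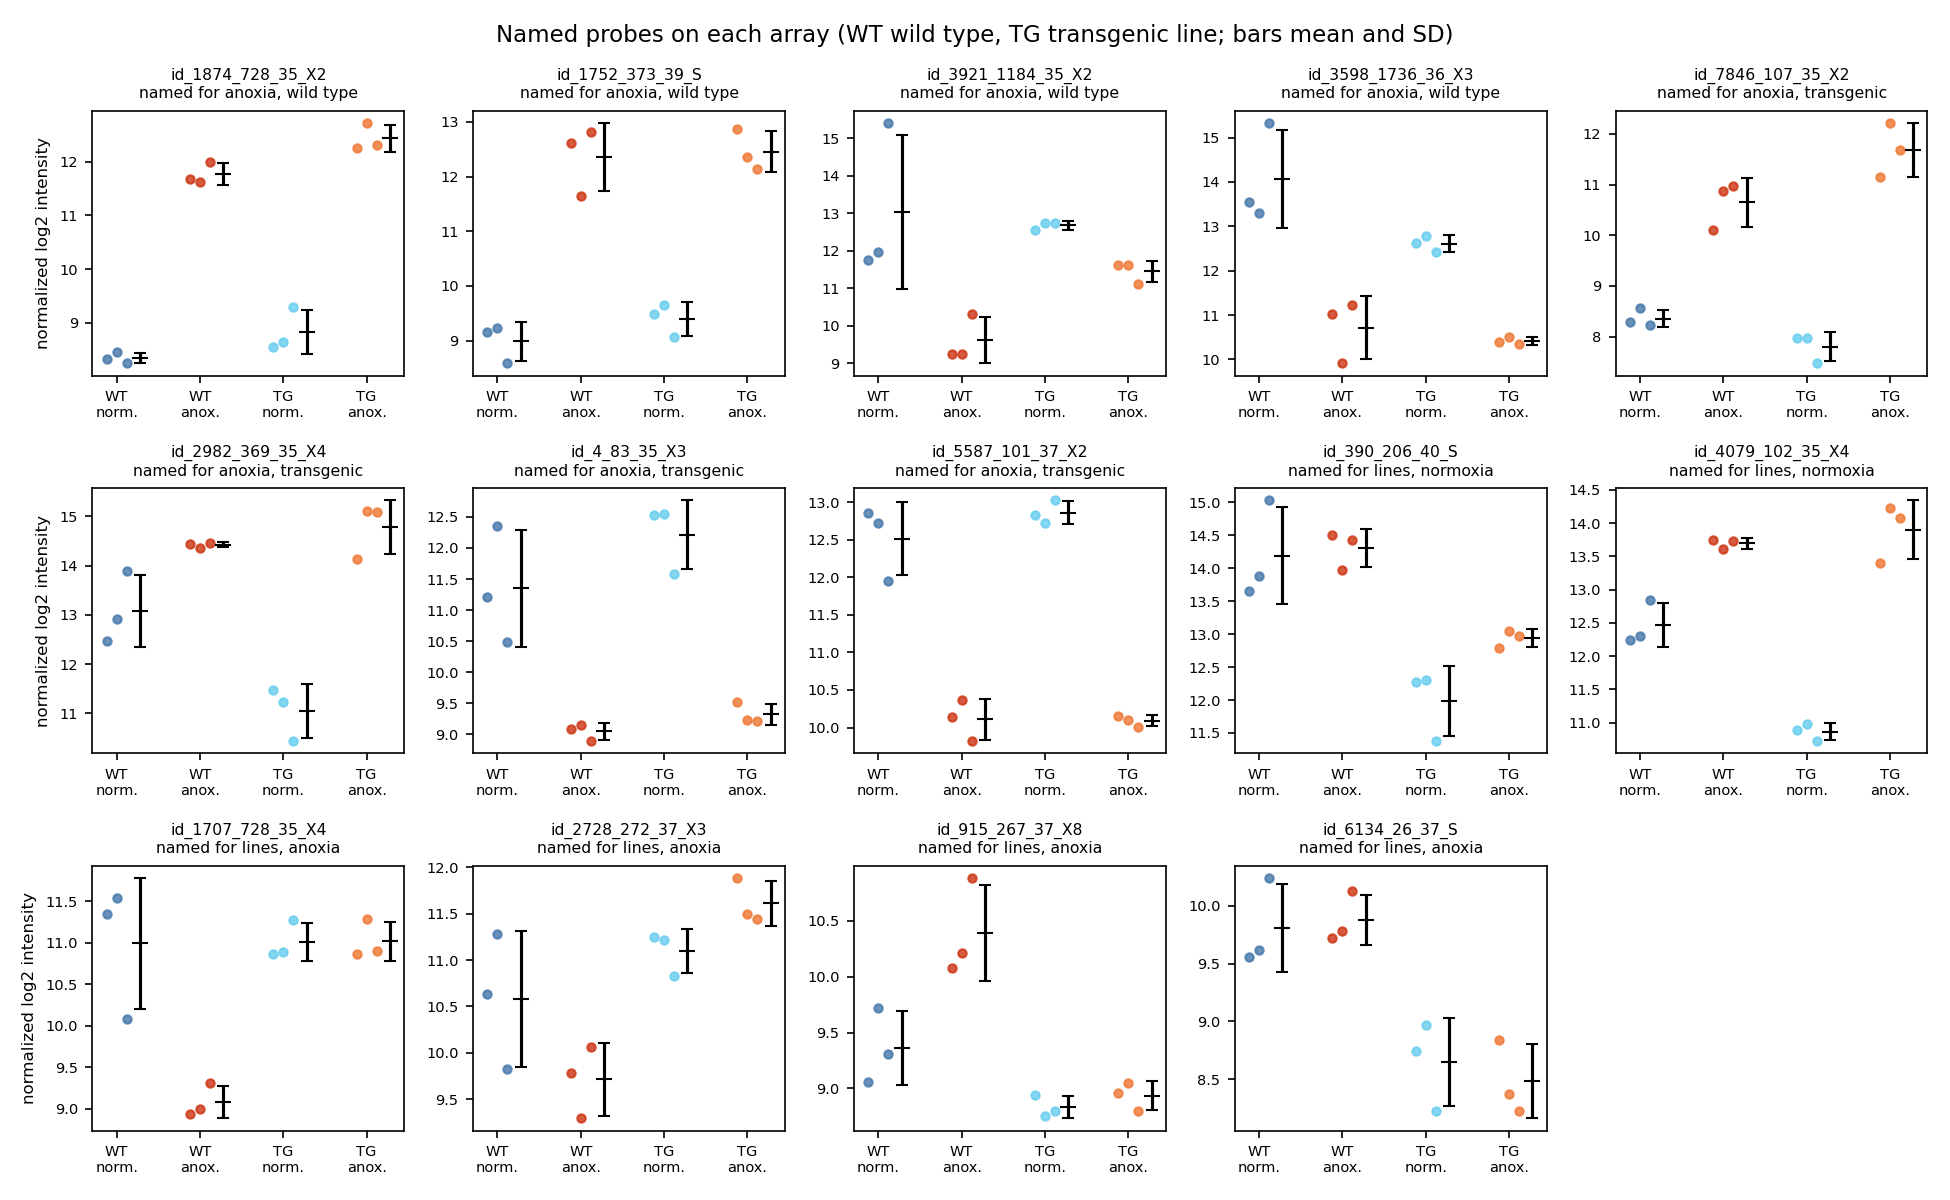
Normalized log2 intensity of the 14 named probes on each of the 12 arrays (points), with the mean and SD of each group of 3 (bars); axes differ between panels and do not start at 0. For the probe id_1874_728_35_X2 all anoxia arrays of both lines lie above all normoxia arrays, and for id_1707_728_35_X4 the 3 wild-type anoxia arrays, all below the limit, lie under those of the transgenic line, which average 11.02.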

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

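Tile removal, its combination with the chip block, quantile normalization of the authors' values and the fit without 2 arrays of raised background were chosen after the data were examined. For the named probes, whose values under array weights, chip, scan day, trend and robust, median of spots and only 6 arrays were also added then, 337 alternative values kept their direction and call, 82 kept the direction only and none reversed. The chip as a fixed block and the median of spots each ended all 4 named calls for the lines in anoxia and both in normoxia. The authors' values on log2, unscaled, gave 1 call for anoxia in wild type, 3 for anoxia in the transgenic line and 0 for each line difference, and moved the median log2 fold change of all tested probes to -0.34 (wild type), 0.19 (transgenic line), -0.58 (lines in normoxia) and 0.02 (lines in anoxia); quantile normalized, they kept each count within 1.5 times, with 233 higher and 338 lower in wild type and 16 and 6 for the lines in anoxia. Only the 6 arrays compared gave 180, 704, 0 and 10 (in the order anoxia in wild type, anoxia in the transgenic line, lines in normoxia, lines in anoxia). With the interaction last, array weights gave 1055, 1008, 73, 140 and 468. They split wild type into 360 higher and 695 lower, and the transgenic line into 593 higher and 415 lower. The chip as a fixed block gave 241, 65, 0 and 0, and as a random block 0 for the lines in normoxia. Scan day as a random block (estimated correlation -0.26) gave 898 in wild type, 81 for the lines in anoxia and 56 for the interaction. The median of spots gave 273, 183, 0 and 0, and the 2-fold threshold 315 in wild type. For the lines in normoxia, 75th percentile scaling, cyclic loess, no filter and the replicate block gave 0 each; the block changed no other total by over 1.5 times but left 1 probe lower for the lines in anoxia in place of 3, and its wild-type anoxia count was 397. The stricter filter gave 17 interaction calls. With tile medians removed, the transgenic line gave 432 and the interaction 1, and wild type split into 242 higher and 421 lower and the lines in anoxia into 18 and 9; with the chip as well, the counts were 250, 107, 0 and 0. Without both arrays of raised background, leaving a lone wild-type anoxia array assumed to vary like the others, they were 849, 443, 0, 696 and 202. The array left was wild-type anoxia replicate 2, which had the lowest array weight (0.198). Its range over the row bands (2.82 log2 units) and its median SD between the spots of one probe (1.14) were the highest. The assumption that it varied like the others is therefore doubtful. The counts for anoxia in wild type, the lines in anoxia and the interaction rest on that array, so no conclusion is drawn from them. With no filter the lines' anoxia responses correlated at 0.35. The cause was not tested for these, apart from the calls lost for the lines with the chip block: in normoxia its fold changes, its SEs or its degrees of freedom alone each left 0 of the 2.

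Leaving out each array in turn gave 259 to 718 calls for anoxia in wild type, 116 to 439 for anoxia in the transgenic line, 0 to 5 for the lines in normoxia, 0 to 51 for the lines in anoxia and 0 to 87 for the interaction, and correlations of 0.47 to 0.62 for the anoxia responses and -0.19 to 0.10 for the line differences. Cyclic loess changed the split in wild type to 133 higher and 290 lower, and in the lines in anoxia to 13 and 5, against 73 and 402, and 19 and 3. The gene lists and their alternatives were not run, since no probe is paired with a gene. Of the target probes, 4056 did not exceed the negative-control limit on enough arrays and were not tested.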

Other observations

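The tests of tile removal, of probe GC content with each array's mean kept, of centring on the tested probes, of what ended the line calls in anoxia, of the pair of arrays on one chip, of the folds behind the averaged line effect, and of other splits for the 5 planned comparisons were chosen or known after the results were seen. Averaged over both lines, anoxia changed 625 probes (182 higher, 443 lower), 847 with the chip as a fixed block and 802 with the spatial trend removed. Of 100 drawn splits of the condition within each line, 1 gave as many, the real one. The highest other gave 129, so a chance share is under 5 percent. The splits took no account of chip, scan day or the numbered pairs in wild type, so they cannot part anoxia from these. Averaged over both conditions, the lines differed at 4 probes (1 higher and 3 lower in the transgenic line). Of 100 drawn splits, 2 gave as many, the highest other being 5, so a chance share is under 5 percent. These splits too took no account of chip and scan day. With the spatial trend removed 9 were called (2 higher, 7 lower). With the chip as a fixed block limma called 0, with 263 at an unadjusted p under 0.05 against 323 without the block. The median size of the 4 was then 1.26 on the log2 scale (median SE 0.22), against 1.31 (0.20). They are id_390_206_40_S, id_6134_26_37_S and id_915_267_37_X8, lower, and id_1706_433_38_X5, higher, the last named after its values were seen.

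For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In wild type the real split gave 475 calls for anoxia and the highest other 4, and of the 4 splits that part all 3 numbered pairs the highest other gave 0. In the transgenic line these were 283 and 0, for the lines in normoxia 2 and 1, and for the lines in anoxia 22 and 6. In each of these 1 of 10 splits, the real one, reached the real count. For the interaction the real count is 0, which each of the 100 drawn splits reaches whatever it gives (the highest other gave 5), so the splits decide nothing there.

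In wild type, anoxia calls were mostly lower, at 84.6 percent. The share was 72.5 percent without wild-type anoxia replicate 2, 73.5 without replicate 3 and 89.2 without replicate 1. It was 68.6 percent with cyclic loess, 65.9 percent with array weights and 88.8 percent with the chip as a fixed block. With no background correction or plain subtraction the lowest share was 83.4 percent, so the share did not rest on the choice of correction. Quantile normalization followed in each setting and evens out a uniform background. The settings could therefore hardly differ on a uniform background, which leaves the order of the spots as it was. Any part of the raised background of 2 anoxia arrays that was not uniform stays open as a source. With each array's trend on probe GC content removed the share was 82.6 percent, which argues against GC content. The test first planned also removed each array's mean, which centres the arrays, and gave 61.3 percent. With the spatial trend removed the share was 63.5 percent, because the higher calls numbered 242 in place of 73. The lower calls, 421 against 402, did not become fewer, but such totals do not show that the same probes were called. Whether the trend was a source of lower calls, or hid higher ones, stays open. With each array centred on its tested probes the share was 69.4 percent. Centring itself moves the share towards even, so this decides nothing about unequal medians. The scan day, which the 3 wild-type anoxia arrays shared with no other group, cannot be told apart from anoxia here. A greater number of lowered transcripts in wild type stays open and was not tested apart from these.

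The 22 line differences in anoxia ended as calls with the chip as a fixed block, yet the median of their fitted log2 differences, 8 of them against a group below the limit, was 97.1 percent of its value without the block (1.40 against 1.44), while the median SE rose from 0.27 to 0.32. Without wild-type anoxia replicate 2 it was 95.8 percent. The fitted sizes of these probes thus hardly changed with the block or without that array. The probes were chosen by their calls on the same arrays, so these shares do not exclude the chip or that array's spatial gradient as a source. The 11 probes called without the 2 arrays of both lines on one chip differed between those arrays by a median of 0.90 (0.08 to 1.43), or 51.4 percent of the 1.74 in the fit without them, by which the probes were chosen. That is 1 pair of arrays, and a part played by the chip stays open. With only the fold changes taken from the chip fit 21 probes were called, with only its SEs 1 and with only its lower degrees of freedom (9.47 against 14.56) 0, so the larger error and the lost degrees of freedom each sufficed to end nearly all calls. Without wild-type anoxia replicate 2 no single part did: the fold changes alone left 24 calls, and the SEs and degrees of freedom together 12. The scan day, on which the wild-type anoxia arrays were read without any other group, cannot be told apart from the line here. A difference between the lines remains a hypothesis, as does an array effect that was not tested.

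The correlation of the lines' anoxia responses was 0.54 with the chip as a fixed block and 0.56 with the spatial trend removed, against 0.56 without either, so neither is a likely cause of it. A shared response of both lines to anoxia is a candidate explanation that these tests leave open.

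Arrays of different groups on one chip deviated together more than arrays on different chips: the mean correlation of deviations was 0.13 over 10 pairs and -0.03 over 44 pairs, with a one-sided permutation p = 0.0312 from 100000 relabellings of the chips. Of the authors' values, those of wild-type anoxia replicate 2 correlated with this array's values at 0.947, and at 0.963 once the spatial trend was removed.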
